A study of Mus musculus with 4 samples.

How the data were processed

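Gene expression was measured on 4 Affymetrix 3′ IVT perfect-match mouse arrays, each hybridized with biotin-labelled RNA made from 200 ng of total RNA of whole inguinal mammary gland at postnatal day 10. Per the labels, 2 arrays came from mice lacking Mt2-mmp (gene symbol Mmp15, a membrane-anchored matrix metalloproteinase) in every tissue and 2 from wild-type littermates, all congenic on C57BL/6J. The labels call the arrays of one genotype biological replicates. They do not say whether an array holds RNA of 1 mouse or of several, nor the sex of the mice, nor which part of the gene was deleted.

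The deposited values are log2 expression values per probe set made by the authors with RMA from the affy package, per the submitters' processing notes. Versions and settings are not given in the sources used here. RMA as a method subtracts a background estimate, forces the arrays to one distribution of probe intensities and summarises the probes of each set, so a change shared by most genes would be removed, and fold changes of dim genes are compressed. The medians of the 4 arrays lay between 5.19 and 5.21, and nonspecific control probe sets had medians of 3.26 to 3.28. For arrays, the number of arrays, not a read depth, limits the precision: the median standard error of a log2 fold change was 0.080, and the median 95% interval reached 0.206 on either side.

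The file held 45141 probe sets, of which 104 were array controls. In the platform annotation used here 28898 probe sets had 1 gene symbol, 551 had several and 15588 others were not listed. Symbols were checked by gene ID against the RefSeq annotation of assembly GRCm38.p6, which matched 99.3% of them and changed 0. That annotation was used only for names and for the order of genes along chromosomes. Where a gene had several probe sets (7180 genes), the one with the highest mean over the 4 arrays was used, which left 17097 genes. No probe set in the annotation was named Mmp15, so the planned check of the genotype labels on the targeted gene was not analysed here.

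Knockout was compared with wild type with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, without covariates or a filter on dim genes, and p-values were adjusted by Benjamini-Hochberg over all genes. The 2 residual degrees of freedom were supplemented by 2.96 prior degrees of freedom. An exact permutation test of 2 against 2 arrays cannot give a p below 0.333, so all p-values rest on the limma model. For 24 gene lists covering mammary cell types, pathways, other cells of the dissected tissue and the chromosomal neighbours of Mmp15, members were counted past the threshold of 0.05 over all genes and adjusted over the list alone. Each list was also tested against all other genes with camera at a preset correlation of 0.01, adjusted over the lists. The lists, the tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule named, in each direction, up to 12 genes past the threshold, filled up with the genes of smallest unadjusted p and skipping predicted genes and clones, then up to 4 members of smallest p in each list, and all members of the metalloproteinase list at an unadjusted p under 0.05.

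The alternatives were quantile normalization, median centring, the brighter genes only, the mean of a gene's probe sets, an intensity trend or robust variances in eBayes, the replicate number as a block, each array left out in turn, every probe set tested separately, a fold threshold, camera with an estimated correlation and fry. A crossed pairing and a covariate for hair follicle genes were added after the data were seen.

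The steps were tested on simulated data with 200 of 17097 genes changed in each of 10 runs. With gene variances drawn from the fitted prior, limma called 9% of changes of 0.5 on the log2 scale, 85.4% of changes of 1 and 95.6% of changes of 1.5, and 4.81% of its calls were unchanged genes. These shares hold for 200 changed genes, because the Benjamini-Hochberg cut tightens when fewer genes change. In the data 24 genes differed by at least 1 and 1 of them passed, so the shares do not show that other changes of that size are absent. A first version of this simulation, which used each gene's moderated variance and so too narrow a range of variances, called 62.4% of changes of 0.5, with 8.77% of calls being unchanged genes; it was replaced after its result was seen because its variances did not follow the model. Camera at the preset correlation gave a p under 0.05 for 100% of simulated lists of 20 independent genes shifted by 0.3 and for 4% of unshifted lists. Genes of the real lists were not independent. In the lists that passed, the estimated correlation ran from 0.019 (immediate early genes) to 0.876 (interferon response), with 0.025 for the luminal, 0.640 for the brown and beige adipocyte and 0.672 for the matrix list. The 4% therefore does not hold for lists of correlated genes, where the preset correlation calls too many. With an estimated correlation camera also falls back on the 2 residual degrees of freedom, so few lists can pass. The basal list had an estimated correlation of 0.0093, under the preset 0.01, yet its unadjusted camera p went from 0.037 to 0.171. A call lost in this way shows neither that a list changed nor that it did not. Figures were drawn with matplotlib 3.10.9.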

Results

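Expression was profiled in whole inguinal mammary gland of 10-day-old mice, 2 arrays from Mt2-mmp knockouts and 2 from wild-type littermates. At this age the gland is a small epithelial tree in a fat pad that also holds stroma, vessels and immune cells. Across genes the arrays correlated between 0.994 and 0.997, and the correlation was 0.995 within the knockout pair and 0.995 within the wild-type pair. Y-linked genes had mean log2 values of 3.58 to 3.64, near the nonspecific controls, while Xist, the RNA that coats the inactive X chromosome, lay between 11.95 and 12.01 in all 4 arrays. All values are RMA log2 values as deposited, and fold changes are knockout over wild type, n = 2 arrays per genotype. The targeted gene itself was not analysed here, because no probe set was named for it, so the genotype labels were not checked on it.

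The comparison asks how loss of Mt2-mmp changes gene expression in the early postnatal gland. A single gene, Gadd45gip1, passed the threshold among 17097. Gadd45gip1, which encodes a protein of the mitochondrial ribosome, fell 2.85-fold: its log2 value was 7.44 ± 0.024 in knockouts and 8.95 ± 0.006 in wild type (SD, n = 2 arrays each), a log2 fold change of -1.51 (SE 0.063, adjusted p = 0.0451 by limma). A dim second probe set of Gadd45gip1, with log2 values of 4.17 to 4.63, differed by 0.27 in the opposite direction (limma adjusted p = 0.764 over all probe sets). The gene lies on chromosome 8, 101 measured genes from Mmp15. No gene passed the threshold in the higher direction, which does not show that none rose. At an unadjusted p under 0.05 limma gave 1198 genes, 620 higher and 578 lower in knockouts, where chance gives 854.85, and 24 genes differed by at least 1 on the log2 scale. The values of both genotypes did not overlap in 37.6% of genes, against 33.3% by chance. The call of Gadd45gip1 was lost when any 1 array was left out (adjusted p of 0.403 and 0.410 without knockout 1 and 2, 0.125 and 0.215 without wild type 1 and 2), and leaving out wild type 1 called Lep instead. The difference itself held, at -1.49 to -1.53 with a SE of 0.087 to 0.093, so the lost call comes from the smaller design, in which a genotype with 1 array is taken to vary like the other. With the replicate number as a block 0 genes passed, and 1185 had an unadjusted p under 0.05 by limma (Gadd45gip1 adjusted p = 0.716, over a range of 0.0134 to 0.716 across alternatives). In that fit Gadd45gip1 still had a log2 fold change of -1.51 (SE 0.062).

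The genes of smallest p after Gadd45gip1 did not pass (adjusted p of 0.114 to 0.651 by limma) and are given as values. Among those lower in knockouts, Cyp2e1, a cytochrome P450 that oxidises ethanol and fatty acids, had a log2 fold change of -1.53 (SE 0.121), and Acot1 and Acot2, which release fatty acids from coenzyme A, had -1.26 (SE 0.136) and -0.98 (SE 0.103). Itih4, a secreted acute-phase protein, was 3.35-fold lower (-1.74, SE 0.102, adjusted p = 0.114). Irx3, a homeobox transcription factor, had -0.82, Ldb3, a protein of the muscle Z-disc, -0.84, and Egln3, an oxygen-sensing prolyl hydroxylase, -0.56. Across all their probe sets the values ran from -0.84 to -0.003 for Ldb3, -0.98 to -0.15 for Acot2 and -0.56 to -0.39 for Egln3. The other genes on the lower side, Hpd, Mpst, Dio3os and Stfa2l1, lay between -0.73 and -0.48. On the higher side Tmem45b, a membrane protein, was 5.35-fold higher (2.42, SE 0.330), with wild-type arrays at 7.26 and 6.30. Npr3, the clearance receptor for natriuretic peptides, had a log2 fold change of 1.44 (SE 0.223), Ucp3, a mitochondrial uncoupling protein, 0.63, and Cebpb, a transcription factor of adipocyte differentiation, 0.51. Fmr1, Fam20c, Klhdc7a, Abat, Dusp10, Iffo2, Tnpo2 and Enc1 lay between 0.43 and 0.75. Dimmer probe sets of these genes went down to -0.08 for Enc1, 0.04 for Tnpo2, 0.09 for Abat and 0.10 for Fmr1. The lowest were 0.27 for Dusp10, 0.33 for Iffo2 and 0.34 for Fam20c. Probe sets of Cebpb ran from 0.08 to 0.63, and the lowest of Ucp3 and Npr3 had 0.26 and 0.64. Tnpo2 and Irx3 lie on chromosome 8, 84 and 46 measured genes from Mmp15.

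**Figure D1:**
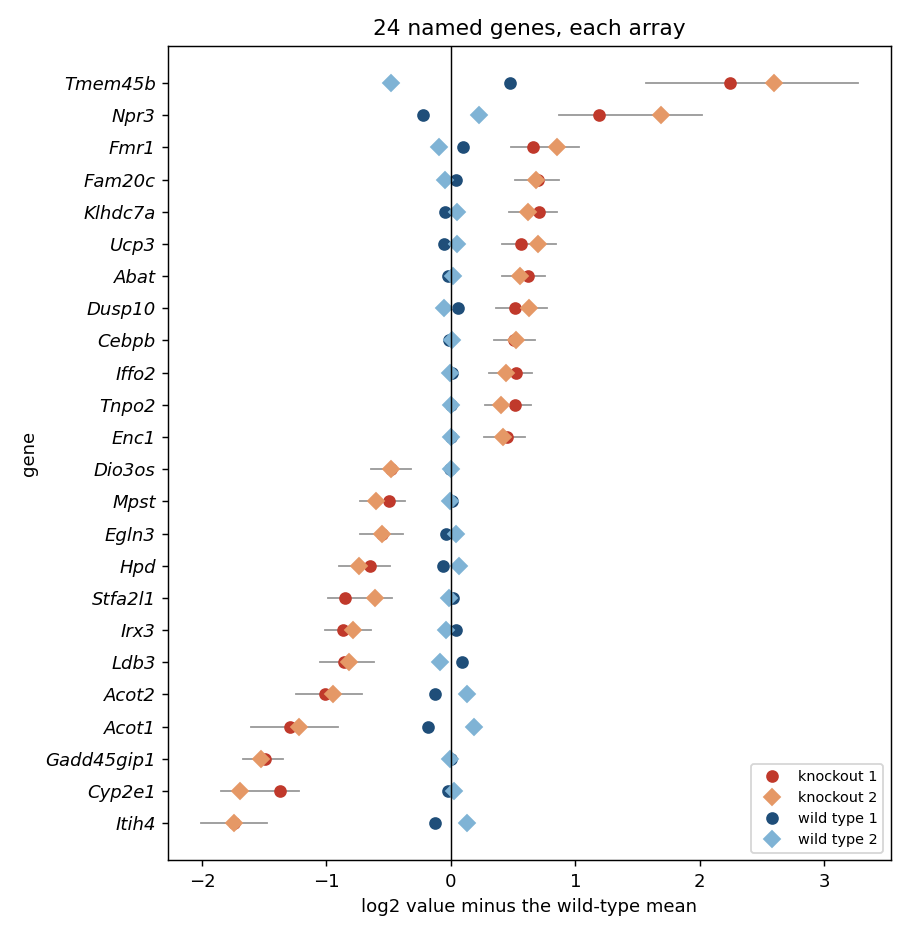
Log2 value of each array minus the wild-type mean for the 24 genes named by rule, 1 line per gene, with the 95% interval of the limma fold change drawn as a grey bar. Gadd45gip1 sits at -1.51 with both knockout arrays close together; the wild-type arrays of Tmem45b are the farthest apart.

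Luminal epithelial genes lay lower in knockouts. Of 27 measured luminal markers 22 had a fold change below 0, with a median of -0.16. Examples were Foxa1, a pioneer factor of hormone-responsive cells (-0.39, SE 0.088), Krt8, a luminal keratin (-0.33, SE 0.091), Epcam, an epithelial adhesion molecule (-0.31, SE 0.063), and the tight-junction gene Cldn3 (-0.24, SE 0.063). The dimmer probe sets of Epcam and Cldn3 had -0.05 and -0.09, and that of Krt8 had -0.31. No member passed over all genes and 0 passed adjusted over the list alone. By camera the list differed from other genes (adjusted p = 1.61e-05), a call lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation). Without knockout 2 the median was -0.068, and with the mean of probe sets it was -0.102, with the call kept in both cases (camera adjusted p = 0.0231 and 0.000145). Of 16 basal and myoepithelial markers 12 were below 0, with a median of -0.11, among them the oxytocin receptor Oxtr (-0.36), the hemidesmosome collagen Col17a1 (-0.29), Krt14 (-0.27) and Lama3 (-0.22). Dimmer probe sets had -0.08 for Oxtr, -0.14 for Krt14 and -0.0004 for Lama3. The basal list did not pass (camera adjusted p = 0.0799; adjusted p = 0.781 with an estimated correlation), 0 members passed over all genes or adjusted over the list alone, and the result depended on single arrays. The basal median was -0.264 without knockout 1 and -0.254 without wild type 1, where the list passed (camera adjusted p = 0.00505 and 0.0190), and 0.013 without knockout 2 and 0.0007 without wild type 2, where it did not. The list also passed with 2 models chosen after the data were seen, a block that pairs knockout 1 with wild type 2 (camera adjusted p = 0.0162) and the hair follicle covariate (0.00420). Some basal markers followed the hair follicle signal described further on rather than genotype: Perp, a desmosome-associated protein, had log2 values of 9.18 in knockout 1 and 9.04 in wild type 2 against 6.20 in knockout 2 and 6.42 in wild type 1, and Dsp, desmoplakin, had 9.91 and 9.94 against 7.44 and 7.85. The 37 branching growth factors and receptors had 17 members above and 20 below 0 (median -0.017, camera adjusted p = 0.584), with Fgfr2, a receptor for stromal fibroblast growth factors, at -0.36 and 0 members past the threshold, adjusted over the list alone or over all genes. The 3 probe sets of Fgfr2 ran from -0.36 to -0.07. With 1 array left out the branching median ran from -0.065 (without knockout 1) to -0.003 (without knockout 2).

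Stromal matrix genes lay slightly higher in knockouts. Of 31 fibrillar and interstitial matrix genes 26 were above 0, with a median of 0.065, including Loxl1, an elastin and collagen crosslinking enzyme (0.26), the microfibril protein Mfap5 (0.20), the crosslinking enzyme Lox (0.19) and Col1a1, a chain of type I collagen (0.18). By camera the list differed from other genes (adjusted p = 0.00605), but not with an estimated correlation (adjusted p = 0.811 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The matrix median was 0.029 without knockout 2 and 0.0061 without wild type 2, and the call was lost in both cases (camera adjusted p = 0.807 and 0.685), while it was 0.117 without knockout 1 and 0.113 without wild type 1. Matrix metalloproteinases and their inhibitors, 20 genes, were split evenly with 10 on each side of 0 (median -0.008, mean 0.017, camera adjusted p = 0.625 toward higher values, so the median and the test differ in sign). Within this list Mmp9, a gelatinase, was the only member at an unadjusted p under 0.05 (0.18, limma adjusted p = 0.712). The log2 values of Mmp9 were 5.16 to 5.38, and its dimmer probe set had a fold change of 0.07. Mmp3, a stromelysin, had 0.36, Mmp23 had 0.19 and Timp2 had 0.11, and 0 members passed over all genes or adjusted over the list alone. Mmp14, another membrane-anchored member, and Mmp2, a gelatinase, chosen after their values were seen, had log2 fold changes of -0.02 and -0.02. Without wild type 2 Mmp14 was at 0.0016 and Mmp2 at 0.018. The median of the metalloproteinase list lay between 0.0025 and 0.027 with 1 array left out. The basement membrane list had 14 of 17 members above 0 (median 0.087, camera adjusted p = 0.0597), with Lamb2 at 0.27, and no member passed over all genes or adjusted over the list alone. Its median was 0.016 without wild type 2, 0.020 without knockout 2 and 0.142 without knockout 1.

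**Figure D2:**
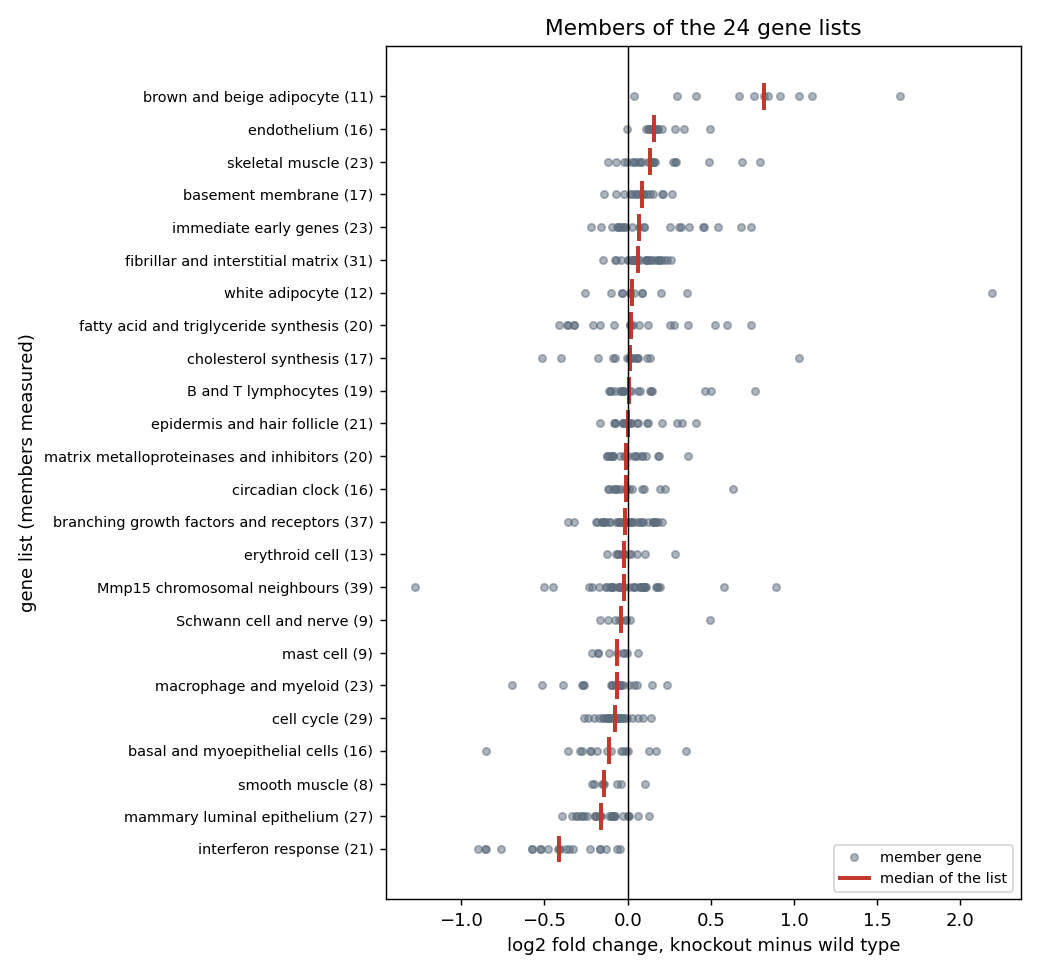
Log2 fold change, knockout minus wild type, of each member of the 24 gene lists, with the median as a red line and the number of measured members in brackets. The brown and beige adipocyte list has the highest median (0.82) and the interferon list the lowest (-0.41).

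Genes of brown and beige fat were higher in knockouts. All 11 measured members lay above 0, with a median of 0.82, and 8 passed adjusted over the list alone, while 0 passed over all genes. Ucp1, the uncoupling protein of thermogenic fat, was 3.11-fold higher (1.64, SE 0.274), the thyroid hormone deiodinase Dio2 2.05-fold (1.03, SE 0.185), the nuclear receptor Ppara 1.79-fold (0.84, SE 0.201) and the respiratory chain subunit Cox7a1 1.77-fold (0.82, SE 0.145). The 3 probe sets of Dio2 ran from 0.08 to 1.03 on the log2 scale, and the 3 of Ppara from 0.83 to 0.96. By camera the list differed from other genes (adjusted p = 2.12e-09), a call lost with an estimated correlation (adjusted p = 0.781 with an estimated correlation). The median was 0.38 without knockout 1 and 1.13 without knockout 2. Of 12 white adipocyte genes 8 were above 0 (median 0.027, camera adjusted p = 0.252), with Lep, the adipocyte hormone leptin, 4.56-fold higher (2.19, SE 0.487) and wild-type arrays at 6.72 and 5.20, and with Plin4, a lipid droplet coat protein, at 0.36. No white adipocyte gene passed over all genes or adjusted over the list alone. Fatty acid and triglyceride synthesis (20 genes) went both ways (median 0.019, camera adjusted p = 0.783): Dgat2, which makes triglyceride, had 0.53 and Thrsp, a lipogenic regulator, 0.36, against -0.32 for fatty acid synthase (Fasn) and -0.32 for the citrate carrier Slc25a1, and 0 passed over all genes or adjusted over the list alone. In cholesterol synthesis (17 genes, median 0.015, camera adjusted p = 0.783) 2 enzymes fell when adjusted over the list alone, Fdft1 (-0.51, SE 0.105) and Lss (-0.40, SE 0.077), and 0 over all genes, while Hmgcs1, at the head of the pathway, had 1.03 (SE 0.314). The log2 values of Hmgcs1 were 7.03 and 7.92 in knockouts 1 and 2 against 6.64 and 6.25 in wild type 1 and 2.

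Interferon-response genes were lower in knockouts. All 21 measured members were below 0, with a median of -0.41, among them the interferon-induced genes Ifit2 (-0.52) and Mx1 (-0.35), the guanylate-binding protein Gbp2 (-0.41) and Oasl1 (-0.23). Mx1 was dim, with log2 values of 3.72 to 4.17 that lay near the nonspecific controls. By camera the list differed from other genes (adjusted p = 3.82e-08), a call lost with an estimated correlation (adjusted p = 0.811 with an estimated correlation), and 0 members passed over all genes or adjusted over the list alone. The difference leaned on wild type 2, whose list median lay 0.483 above the mean of all arrays against -0.074 for wild type 1. Knockout 2, at -0.078, was level with wild type 1, and knockout 1 was at -0.332. Without wild type 2 the list median was -0.142, and without wild type 1 it was -0.688. Macrophage and myeloid markers had 18 of 23 members below 0 (median -0.065, camera adjusted p = 0.0193; adjusted p = 0.811 with an estimated correlation), including S100a9 (-0.52), a neutrophil calcium-binding protein, Mpeg1 (-0.39), Ctss (-0.27) and Cd14 (-0.26), and the median was 0.0017 without knockout 1, -0.153 without knockout 2 and -0.105 without wild type 2. The macrophage call was lost without knockout 1 (camera adjusted p = 0.891) and without wild type 1 (0.0540). No macrophage gene passed over all genes or adjusted over the list alone. B and T lymphocyte markers were evenly split (10 of 19 above 0, median 0.0062, camera adjusted p = 0.167). The B-cell genes Ms4a1 (0.76) and Cd79b (0.50) were at the upper end, and the dimmer probe set of Ms4a1 had 0.21. In the lymphocyte list 0 members passed over all genes or adjusted over the list alone.

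Endothelial markers lay higher in knockouts, with 15 of 16 members above 0 and a median of 0.16 (camera adjusted p = 3.14e-05; adjusted p = 0.781 with an estimated correlation). Tie1, an endothelial receptor kinase, had 0.50, the angiopoietin receptor Tek 0.18, Sox17 0.18 and Flt1 0.17, and 0 members passed over all genes or adjusted over the list alone. The log2 values of Tie1 were 7.82 and 8.35 in knockouts 1 and 2 against 7.68 and 7.51 in wild type 1 and 2. The endothelial median was 0.083 without knockout 2, where the call was lost (camera adjusted p = 0.155). Skeletal muscle genes had 19 of 23 members above 0 (median 0.136, camera adjusted p = 0.0310; adjusted p = 0.811 with an estimated correlation), with Myl1 at 0.29 and Mb, myoglobin, at -0.12, and the median was -0.071 without knockout 2. The muscle call was also lost without wild type 1 or 2 (camera adjusted p = 0.0540 and 0.0822), with the brighter genes only (0.467) and with the mean of probe sets (0.0644). Immediate early genes had 13 of 23 members above 0 (median 0.066, camera adjusted p = 0.0325; adjusted p = 0.781 with an estimated correlation), with Egr1 (0.74), Dusp1 (0.68), Junb (0.54) and Nr4a1 (0.32) at the upper end, and the call was lost without wild type 1 (camera adjusted p = 0.229), while the median was 0.199 without wild type 2 and 0.253 with the brighter genes only. In the muscle and immediate early lists 0 members passed over all genes or adjusted over the list alone. Junb lies on chromosome 8, 89 measured genes from Mmp15, among the genes near Mmp15 described further on.

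The remaining lists did not pass. Camera gave an adjusted p of 0.0556 for smooth muscle (8 genes, median -0.145), 0.252 for mast cells (9 genes, -0.064), 0.252 for cell cycle (29 genes, -0.074), 0.552 for epidermis and hair follicle (21 genes, 0.0045), 0.703 for Schwann cell and nerve (9 genes, -0.038), 0.783 for erythroid cells (13 genes, -0.023) and 0.783 for the circadian clock (16 genes, -0.010). Without wild type 1 the smooth muscle median was -0.019 and the cell cycle median 0.359. Without wild type 2 they were -0.164 and -0.511. In these 7 lists 0 members passed over all genes or adjusted over the list alone. Single members at the edge were S100b, a Schwann cell calcium-binding protein (0.49), and Per1, a clock gene (0.64). The log2 values of Per1 were 8.57 and 9.15 in knockouts 1 and 2 against 8.11 and 8.34 in wild type 1 and 2. In all, 8 of 24 lists passed by camera with the preset correlation, 0 with an estimated correlation and 0 by fry. Because the estimated correlation leaves camera only 2 degrees of freedom, the calls lost with it do not decide whether a list changed.

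Among 39 measured chromosomal neighbours of Mmp15 the directions were mixed (19 above and 20 below 0, camera adjusted p = 0.999), yet 4 genes passed adjusted over the list alone and 0 over all genes. Ciapin1, which takes part in iron-sulfur protein assembly, rose 1.86-fold (0.89, SE 0.170) and the kinesin Kifc3 rose 1.49-fold (0.58, SE 0.102). Nlrc5, an activator of MHC class I genes, fell 2.43-fold (-1.28, SE 0.230) and Herpud1, a protein of endoplasmic reticulum-associated degradation, fell 1.37-fold (-0.45, SE 0.091). Of the 4 probe sets of Ciapin1 the fold changes ran from 0.08 to 1.27.

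**Figure D3:**
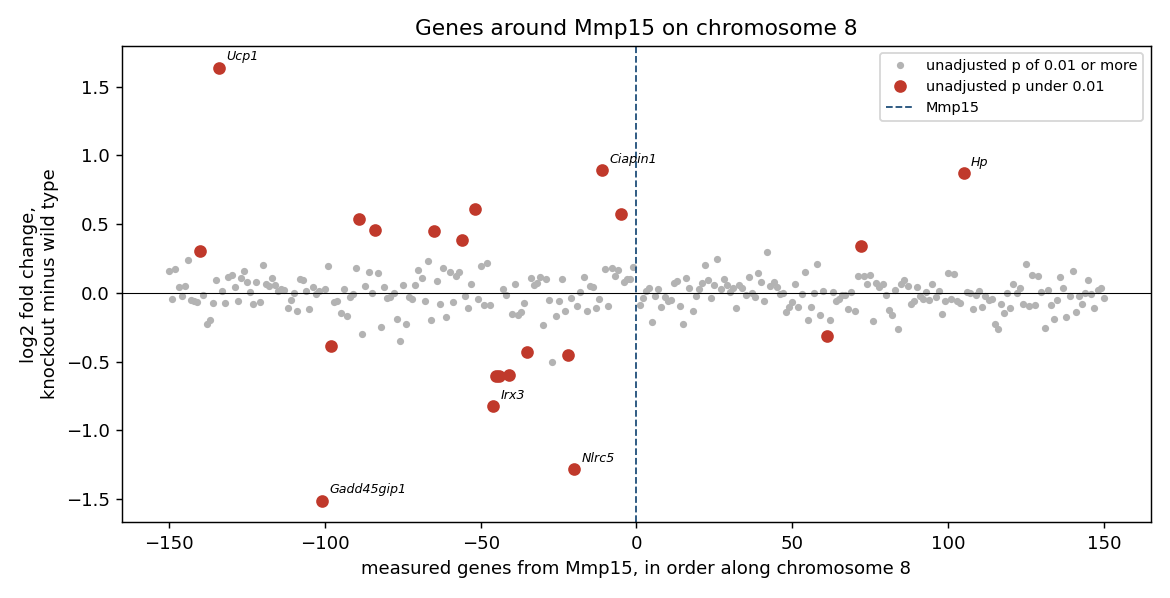
Log2 fold change, knockout minus wild type, of genes up to 150 measured genes from Mmp15 (dashed line), in their order along chromosome 8, with genes at an unadjusted limma p under 0.01 in red. Of these, 18 lie before Mmp15 and 3 after it.

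The arrays also differed within each genotype. Knockout 1 and wild type 2 held high levels of hair follicle genes that were near background in knockout 2 and wild type 1. Krt25, a keratin of the inner root sheath, had log2 values of 10.44 in knockout 1 and 10.47 in wild type 2 against 3.70 and 3.99, and trichohyalin (Tchh) had 10.74 and 10.37 against 3.49 and 4.03. The median of the epidermis and hair follicle list lay 0.394 above the mean of all arrays in knockout 1 and 0.237 above it in wild type 2, and at -0.284 and -0.443 in knockout 2 and wild type 1. Each genotype held 1 array of each kind, so these levels as a covariate could hardly move a difference between genotypes, but Gadd45gip1 no longer passed in that fit (-1.51, adjusted p = 0.164 by limma). Other lists differed between the same pairs of arrays by camera. Lower in knockout 1 and wild type 2 were the matrix (median difference -0.105, adjusted p = 7.23e-09), skeletal muscle (-0.142, 6.41e-06), endothelium (-0.173, 0.000105) and macrophage lists (-0.098, 0.00371), and also cell cycle (-0.459, 5.86e-15), basement membrane (-0.109, 0.00322), mast cells (-0.151, 0.00350), cholesterol synthesis (-0.091, 0.0303) and fatty acid synthesis (-0.122, 0.0362). Higher there were the basal (0.057, 2.29e-05), brown and beige adipocyte (0.311, 0.00792), luminal (0.0067, 0.0303) and interferon lists (0.161, 0.0467). None of these held with an estimated correlation (adjusted p = 0.579 to 0.691 with an estimated correlation). Nor did the epidermis and hair follicle list itself (median difference 0.726, camera adjusted p = 2.03e-25, and 0.172 with an estimated correlation). That form of the test thus missed even the largest list difference between these pairs, so its result does not decide about the other lists. Cell cycle genes also set the wild-type arrays apart, with list medians of 0.507 in wild type 1 and -0.401 in wild type 2 relative to the mean of all arrays.

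**Figure D4:**
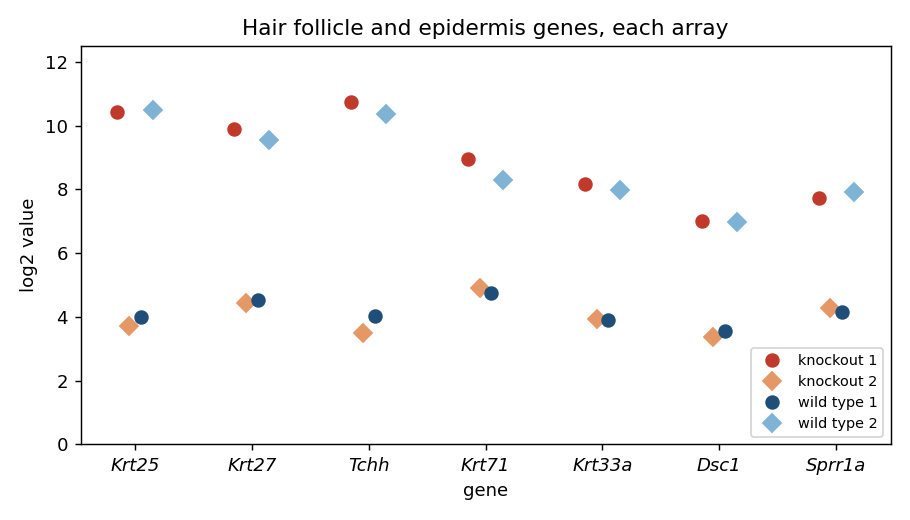
Log2 values in each of the 4 arrays of 7 genes selected from the epidermis and hair follicle list. For every gene shown knockout 1 and wild type 2 lie near 7 to 11 and the other two arrays between 3 and 5, with both genotypes in each pair. By limma 10 of the 21 measured members of the list passed in this split. Others did not follow it, such as Krt1 (3.85 to 3.98) and Krtdap (7.58 to 8.08 across the 4 arrays).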

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

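The test of separate probe sets was planned, and Prdx2 was singled out after its values were seen. Prdx2, a cytosolic peroxiredoxin, has 2 probe sets that disagreed. The brighter one, used in the report, had log2 values of 11.34 in knockouts and 11.15 in wild type (0.18, SE 0.066), while the dimmer one, which the report does not use, was at 5.61 against 8.44, a difference of -2.83 (SE 0.103, adjusted p = 0.022 by limma over all probe sets), or 7.11-fold lower. It is a signal in data outside the main measurement and lies on chromosome 8, 90 measured genes from Mmp15.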

How the results depend on the processing

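The crossed pairing and the hair follicle covariate were chosen after the data were seen. The count of genes past the threshold, 1 as reported, was 0 with the mean of probe sets, the replicate block, the crossed pairing or the hair follicle covariate (limma, with 1185, 1185, 1064 and 1127 genes at an unadjusted p under 0.05), 2 with robust variances (Itih4 added) and 2 with every probe set tested separately (Prdx2 added), and from 0 to 1 with 1 array left out (837 to 1510 at that p); with the other alternatives it was 1. Gadd45gip1 kept its direction in every alternative at the gene level, at -0.62 with the mean of probe sets and -1.53 to -1.49 with 1 array left out. With every probe set tested separately its brighter one had -1.51 and its dimmer one 0.27, the opposite direction. The dimmer one, at log2 values of 4.17 to 4.63, also enters the -0.62. Equal replicate numbers did not pair the arrays (correlation of deviations -0.48 across genes), and the replicate block and the crossed pairing both gave 0 genes. Of 131 named genes 17 changed sign. With the mean of probe sets 4 did: Synpo2 (0.187), Drp2 (0.015), Epb42 (-0.0017) and Prdx2 (-1.32), whose dimmer probe set is low in knockouts. With 1 array left out 13 did, with log2 fold changes between -3.54 and 3.21 for Krt25, -3.71 and 3.54 for Tchh, -1.53 and 1.45 for Perp, -1.46 and 1.01 for Dsp, -0.688 and 0.263 for Fcer1a, -0.660 and 0.134 for Nusap1, -0.307 and 0.047 for Pcna, -0.266 and 0.042 for Cpa3, -0.205 and 0.777 for Slc4a1, -0.180 and 0.025 for Mag, -0.156 and 0.019 for Hba-a2, -0.054 and 0.018 for Mmp2 and -0.046 and 0.0016 for Mmp14. The luminal median (-0.160) and the matrix median (0.065) lost their calls with an estimated correlation and with fry, whose medians are the same by construction. With 1 array left out the luminal median ran from -0.194 to -0.068 (-0.102 with the mean of probe sets, call kept), the matrix median from 0.0061 to 0.117, the basal median from -0.264 to 0.013 (0.0007 without wild type 2) and the metalloproteinase median from 0.0025 to 0.027 (0.011 and 0.020 without wild type 2 and knockout 2), each on the other side of 0 from the reported -0.008. The basal list passed with the crossed pairing (-0.114), the hair follicle covariate (-0.131), without knockout 1 (-0.264) and without wild type 1 (-0.254). With the brighter genes only the metalloproteinase median was 0.036. The medians of 15 of 24 lists changed sign somewhere, 2 of them among the lists that passed: skeletal muscle at -0.071 without knockout 2 (up to 0.194 without knockout 1) and macrophages at 0.0017 without knockout 1 (down to -0.153 without knockout 2). With 1 array left out the medians of the others ran from -0.511 to 0.359 for cell cycle, -0.181 to 0.521 for epidermis and hair follicle, -0.157 to 0.017 for mast cells, -0.144 to 0.149 for cholesterol synthesis, -0.080 to 0.018 for the circadian clock, -0.058 to 0.025 for Schwann cell and nerve, -0.042 to 0.074 for white adipocytes, -0.026 to 0.066 for fatty acid synthesis, -0.011 to 0.018 for erythroid cells and -0.00070 to 0.070 for lymphocytes. The brighter genes only gave -0.066 for lymphocytes and 0.015 for erythroid cells, the mean of probe sets gave 0.0026 for the neighbours of Mmp15, and epidermis and hair follicle was at -0.0014 with median centring and -0.029 with the hair follicle covariate. Of the lists that did not pass as reported, basement membrane passed in 6 alternatives (camera adjusted p of 0.00526 to 0.0400) and smooth muscle in 4 (0.00505 to 0.0390). With 1 array left out, white adipocytes passed without knockout 1 (0.00616), cholesterol synthesis without wild type 2 (0.00647, median -0.144 against the reported 0.015), and cell cycle in opposite directions without wild type 1 (6.99e-15, median 0.359) and wild type 2 (2.92e-34, median -0.511). Further passes were mast cells (0.0291 and 0.0299) and epidermis and hair follicle (0.0108 and 0.00597) without knockout 2 or wild type 2. The cause of these shifts was not tested. The Mmp15 alternatives were not run, since no probe set was named for it, nor the Y-linked covariate, since Y-linked genes were near background in all 4 arrays; robust variances have no counterpart in camera. Signal near background compresses fold changes of dim genes.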

Other observations

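The tests of the chromosome 8 pattern and of the hair follicle pattern, and the single-array and hair follicle tests of brown fat genes, were chosen after the results were seen; the respiratory chain test was set before its result. With 2 arrays per genotype there are only 3 ways to split the arrays, too few for a share under 0.05: 2 of the 3 called as many genes as the genotypes, with 1 gene for the real split and 56 for the highest other, which joins knockout 1 with wild type 2. All 56 genes were higher in those 2 arrays, 24 of them keratins or keratin-associated genes and 10 on the fixed epidermis and hair follicle list, so a structure of the samples other than genotype was larger in count than genotype itself. The third split called 0 genes by limma. At an unadjusted p under 0.05 the order was another, with 1198 genes for genotype, 648 for the split that joins knockout 1 with wild type 2 and 513 for the third.

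Genes near Mmp15 held more small p-values than genes elsewhere. Within 100 measured genes on either side, 17 of 200 genes (8.5%) had an unadjusted limma p under 0.01, against 1.28% on other chromosomes, and chance position is argued against: 0% of 12552 windows of as many neighbouring genes elsewhere held as many, the highest holding 7. These windows overlap and share most of their genes with the next, so they amount to far fewer separate comparisons. The 17 comprised 9 lower and 8 higher genes, such as Irx3 (-0.82), Irx5 (-0.60), Lpcat2 (-0.60), Tox3 (0.61) and N4bp1 (0.45), and 15 of them lay before Mmp15. A chromosome segment from another strain carried along with the targeted allele is a hypothesis that stays open, as does an effect of the deletion on its neighbours: the ratio of 6.62 between the shares is the pattern itself and favours neither, and the strain of origin is not given in the sources used here. Probes that bind less well to a variant sequence cannot be told apart from a true change: of 5 such genes with another probe set above a log2 value of 5, 3 (60%) had one that shared the direction at an unadjusted limma p under 0.05, against 60.7% of 61 genes on other chromosomes, and in all 5 the other probe sets had the same sign. The 5 leave out Gadd45gip1, which lies outside the window at 101 measured genes and had probe sets at -1.51 and 0.27. They also leave out Prdx2, at 90 measured genes, whose brighter probe set had an unadjusted limma p of 0.033. Its probe sets were at 0.18 and -2.83, so in both genes the signs were opposite. The second probe set of Gadd45gip1 had log2 values of 4.17 to 4.63, under the cut of 5 used here, so its sign carries little weight.

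Hair follicle genes were high in knockout 1 and wild type 2. The median difference of the 21 fixed epidermis and hair follicle genes between these arrays and the other two was 0.726 (0.773 within knockouts and 0.679 within wild type), and 3 of the 21 had a mean above log2 5 in the other two arrays, while 0 belonged to another list. RNA degradation is argued against, since the 3′ minus 5′ actin signal differed by 0.00020 between the same pairs of arrays. Hair follicle tissue left in those 2 samples and the stage of the hair cycle in each mouse both stay open: the difference is the pattern itself and favours neither, and dissection and hair growth were not recorded in the labels. The labels give postnatal day 10 for all 4 arrays, so they record no difference in age that would set the hair cycle apart.

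The median of the brown and beige adipocyte list lay above the wild-type mean in both knockout arrays, by 1.13 in knockout 1 and 0.38 in knockout 2. A single array is argued against as the whole cause, by a bound set after the results were seen: the lowest median with any 1 array left out was 0.38. That value, without knockout 1, repeats the one just given for knockout 2. Without wild type 1 the median was 0.63 and without wild type 2 it was 0.85. The hair follicle covariate decides nothing here (median 0.818 with it), because the hair follicle list differed by 0.054 between genotypes and by 1.94 between arrays of one genotype, so the design holds the estimate in place. A larger share of mitochondria-rich brown fat in the knockout samples may contribute but stays open: 72 nuclear-encoded respiratory chain genes had a median of 0.071, with 63 above 0, which lies between the bounds set beforehand, and the median was 0.126 in knockout 1 and 0.0083 in knockout 2 against the wild-type mean. An effect of the genotype on thermogenic fat was not tested separately from these, and Ucp1 itself lies on chromosome 8, 134 measured genes from Mmp15.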
